A study of Mus musculus with 2 samples.

How the data were processed

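RNA of splenic CD4 T cells from wild-type and PINK1 knockout mice was measured, with 1 array for each genotype. Per the labels' protocols, total RNA was extracted with Trizol, and fragmented sense cDNA was labelled at its ends with biotin by terminal transferase for a whole-transcript GeneChip array. The values used are the log2 intensities that the authors deposited in the value table of the series, with 1 value for each of 41345 probe sets on each array. The normalization, background correction, summary of probes and log base are not given in the sources used here. The log base was taken as 2 from the range of the values, 1.08 to 14.3 on the WT array and 1.14 to 14.35 on the PINK1 KO array, so every fold printed rests on that reading. Scanner files and detection calls were not analysed here, and a level filter took their place.

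Probe sets were named through the platform's annotation, which lists 1 gene for 23521 probe sets, several for 1820 and none for 16004. The Entrez IDs of 23328 probe sets with 1 gene matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be changed. The build behind the array is not given in the sources used here, so that table served only for names and for which genes neighbour Pink1. Probe sets with 1 gene were averaged per gene, giving 22180 genes, of which 1082 had more than 1 probe set. Probe sets with several genes or with none listed entered no gene value and are described apart.

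The difference of a gene was its log2 intensity on the PINK1 KO array minus that on the WT array. Counts used the 11090 genes whose mean over both arrays was at or above the median of 4.61, and a threshold of 2-fold. With 1 array per genotype no test between genotypes can be made, so there are no p-values, and the spread between animals is unknown.

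The groups, the thresholds, the alternatives, 37 gene lists and the rule for named genes were fixed before the data were examined. The lists cover the Th17, JAK-STAT3, Th1, Th2, regulatory and follicular helper T cell programs, naive, effector and memory genes, T cell receptor and co-stimulation genes, and early activation and immediate early and heat shock genes. They also cover mitophagy, oxidative phosphorylation, mitochondrially encoded transcripts, glycolysis, the antioxidant, stress and interferon responses, the cell cycle, the circadian clock, glucocorticoid response, ribosomal proteins and housekeeping genes. The rest are markers of B cells, MHC class II, plasma cells, CD8 T cells, NK cells, macrophages, neutrophils, dendritic cells, erythroid cells, platelets, stroma and mast cells, and genes of the sex chromosomes. The median difference of a list was ranked among 10000 random lists of the same size drawn from the same 20 bins of mean level. A list was said to lie apart at or below percentile 2.5 or at or above percentile 97.5, which is a description of these arrays. The lists share some genes and genes are not independent replicates.

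Named genes were Pink1, 18 genes of the STAT3 and T helper pathways, the 12 highest and 12 lowest differences above the level filter, and up to 4 members of each list with the largest absolute difference above the filter. Predicted genes, small RNA genes, olfactory receptors and antigen receptor segments were left out of the 12 highest and 12 lowest. Mki67, Pcna, Rsad2 and Ifit3 in the report, and genes named in the closing section outside these lists, were chosen after their values were seen.

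The alternatives were quantile normalization, centring on the median of all genes, removal of the trend with mean level (loess, span 0.3), other level filters, thresholds of 1.5-fold and 3-fold, the probe set with the highest mean for each gene, each probe set on its own, the mean of a list, lists without their largest member, lists of genes above the filter, and random lists not matched on level. The scripts were tested on simulated data for the PINK1 KO and WT arrays with 11090 genes. Of genes changed 3-fold, 99.0% were found at 2-fold or more in the right direction, and of genes changed 4-fold, 100.0%. Among unchanged genes 0.01% were called, and of 100 lists of 20 genes with no shift 5 lay apart. The simulated differences were independent normal draws with the spread of genes of similar level on these arrays. They hold no added variation between animals or arrays, no heavier tails and no genes that move together. Neither value is therefore an error rate for these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.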

Results

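Total RNA of CD4 T cells from mouse spleen was measured on 2 whole-transcript expression arrays. The control array held wild-type (WT) RNA of the B6 background. The other held RNA from animals without PINK1, the PTEN-induced kinase of the mitochondrial surface that starts the removal of damaged mitochondria (PINK1 KO). There was 1 array per genotype, so no difference below has a replicate check, and "higher" and "lower" describe these 2 arrays. The title of the control sample calls it a knockout, while its source name and genotype call it wild type, and the latter was followed. The culture or stimulation of the cells and the number of mice behind each RNA sample are not given in the sources used here. The log2 intensities of the 41345 probe sets had a median of 4.49 on the WT array and 4.57 on the PINK1 KO array, and the arrays correlated across probe sets with a Pearson r of 0.98. The number of arrays limits the precision.

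The study's title places PINK1 upstream of STAT3 and of Th17 cells, the CD4 T cells that make interleukin 17, and the comparison of the 2 arrays addresses what the loss of PINK1 does to the transcripts of these cells. The interleukin 17 genes Il17f and Il17a were 9.58-fold and 5.05-fold higher on the PINK1 KO array, with Il17a below the level filter of 4.61 on the WT array. Genes of the regulatory T cell program, of the follicular helper T cell program and of the interferon response were also higher as groups. Genes of cell division were lower, with all 29 measured members of the cell cycle list below their WT level. Transcripts of oxidative phosphorylation and glycolysis were lower by small amounts in nearly every member. Their medians lay near that of housekeeping genes, a list that shares Sdha, Gapdh and Pgk1 with them. Markers of macrophages, neutrophils and B cells were higher on the same array.

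Pink1 itself had a log2 intensity of 5.49 on the WT array and 4.71 on the PINK1 KO array, a difference of -0.78, or 1.71-fold lower. This difference lay at percentile 0.9 among genes of similar level. It rests on 1 probe set. The deleted part of the gene is not given in the sources used here, so the probe set may lie outside it and would then check nothing about the labels.

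Of 22180 genes, 11090 had a mean level at or above the median and were used for counts. Among them, 114 genes were 2-fold or more higher and 44 were 2-fold or more lower on the PINK1 KO array, together 1.42% of these genes. Of the 114, 29 had a WT intensity below the level filter, and of the 44, 5 had a PINK1 KO intensity below it, so their folds depend on an unknown background. With the trend of the difference with the mean level removed, the split was 132 higher and 28 lower, which moved the higher share from 72.2% to 82.5%. At 1.5-fold the balance turned, with 400 genes higher and 453 lower (46.9% higher), and at 4-fold 16 genes were higher and 2 were lower. The median difference was -0.071 over the genes used for counts and -0.152 over the tenth of genes with the highest level, so small negative values of abundant transcripts are close to the general level.

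**Figure D1:**
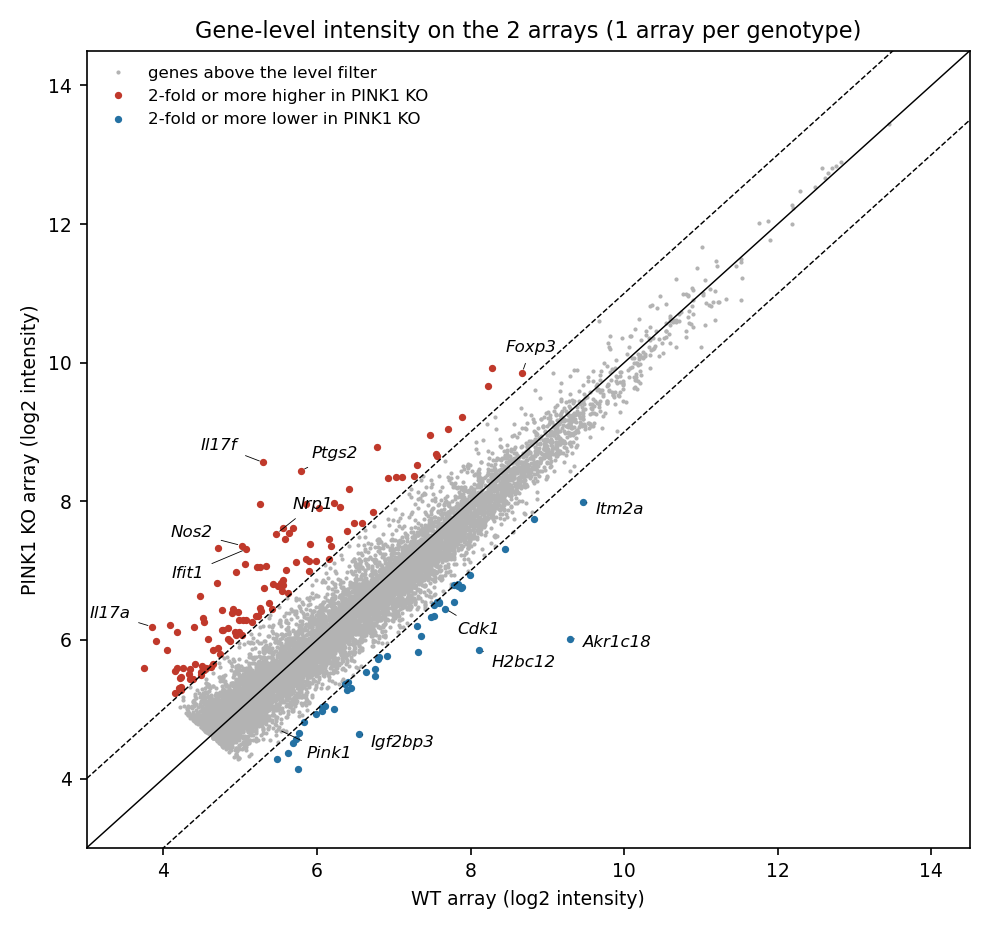
Log2 intensity of each of the 11090 genes above the level filter on the WT array (x axis) and the PINK1 KO array (y axis), with the solid line at equal intensity and dashed lines at 2-fold. Red points mark the 114 genes 2-fold or more higher and blue points the 44 genes 2-fold or more lower, and Pink1 is 1.71-fold lower.

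The highest differences included cytokine, inflammatory and interferon-induced genes. After Il17f (3.26) came Ifi205 (2.70), an interferon-induced gene of the HIN-200 family, and Ptgs2 (2.65), which encodes the prostaglandin synthase COX-2. Nos2, the inducible nitric oxide synthase, and Il17a both differed by 2.34. They were followed by the interferon-induced genes Ifit1 (2.23), Oasl2 (2.12) and Slfn5 (2.12), by Sostdc1 (2.15), a secreted BMP and Wnt antagonist, by the chemokine receptor gene Cxcr4 (2.11), by Il1a (2.09), which encodes interleukin 1 alpha, and by the co-receptor gene Nrp1 (2.06). Il17a, Sostdc1, Slfn5 and Il1a lay below the level filter on the WT array. Nos2, Ptgs2 and Il1a are also known products of activated macrophages, and monocyte and macrophage markers had a median difference of 0.52 on the same arrays.

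The lowest difference was that of Akr1c18, which encodes 20-alpha-hydroxysteroid dehydrogenase. Its log2 intensity was 9.30 on the WT array and 6.02 on the PINK1 KO array, or 9.66-fold lower. The histone genes H2bc12 (-2.25) and H4c9 (-1.49) and the mitotic genes Kif23 (-1.30), Shcbp1 (-1.24), Cdk1 (-1.22), Ska3 (-1.21) and Kifc5b (-1.20) were also among the 12 lowest. The remaining genes of this group were Igf2bp3 (-1.90), an RNA-binding protein of fetal tissues, Pde7b (-1.61), a cyclic AMP phosphodiesterase, Itm2a (-1.47), a membrane protein of T cells, and Fancb (-1.26), a member of the Fanconi anemia DNA repair pathway.

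Il17f and Il17a, the cytokine genes that define Th17 cells, led the Th17 list. Il17f had a log2 intensity of 5.30 on the WT array and 8.56 on the PINK1 KO array, and Il17a 3.85 and 6.19. Il21, a cytokine of Th17 and follicular helper cells, was 0.76 higher, and the chemokine receptor gene Cxcr6 was 0.75 higher. Il23r, the receptor of a cytokine that sustains Th17 cells, was 2.17-fold higher and Il22 was 0.57 higher. Both had a mean over the 2 arrays below the filter, although Il23r was 4.76 on the PINK1 KO array. Rorc, which encodes the lineage factor of Th17 cells, was not analysed here because no probe set lists it alone. Of 18 measured members of the Th17 list, 8 were 1.5-fold or more higher, 10 lay between and 0 were lower. The median of 0.56 was above those of all 10000 random lists matched on level, whose middle 95% ran from -0.17 to 0.13. Without Il17a and Il17f, an alternative chosen after seeing the data, the median was 0.55. Beside this group, the B cell, macrophage and neutrophil lists had medians of 0.31, 0.52 and 0.37.

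Genes of the STAT3 pathway itself differed little. Stat3, the transcription factor that interleukin 6 activates, was 0.20 higher at a log2 intensity of 9.04 on the WT array. The interleukin 6 receptor genes Il6ra and Il6st differed by 0.18 and 0.03, and Socs3, a feedback inhibitor that STAT3 induces, by 0.16. The largest differences among the 23 measured members were those of the kinase gene Tyk2 (0.54), the phosphatase gene Ptpn2 (-0.42), the proto-oncogene Myc (-0.38) and the receptor gene Il10ra (0.34). All 23 lay within 1.5-fold. The median of 0.13 was above all 10000 random lists matched on level, whose middle 95% ran from -0.26 to 0.00, and it lay only at the upper limit of the middle 95% of lists not matched on level. The mean of the list was 0.07. Intensities of transcripts do not measure STAT3 phosphorylation.

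**Figure D2:**
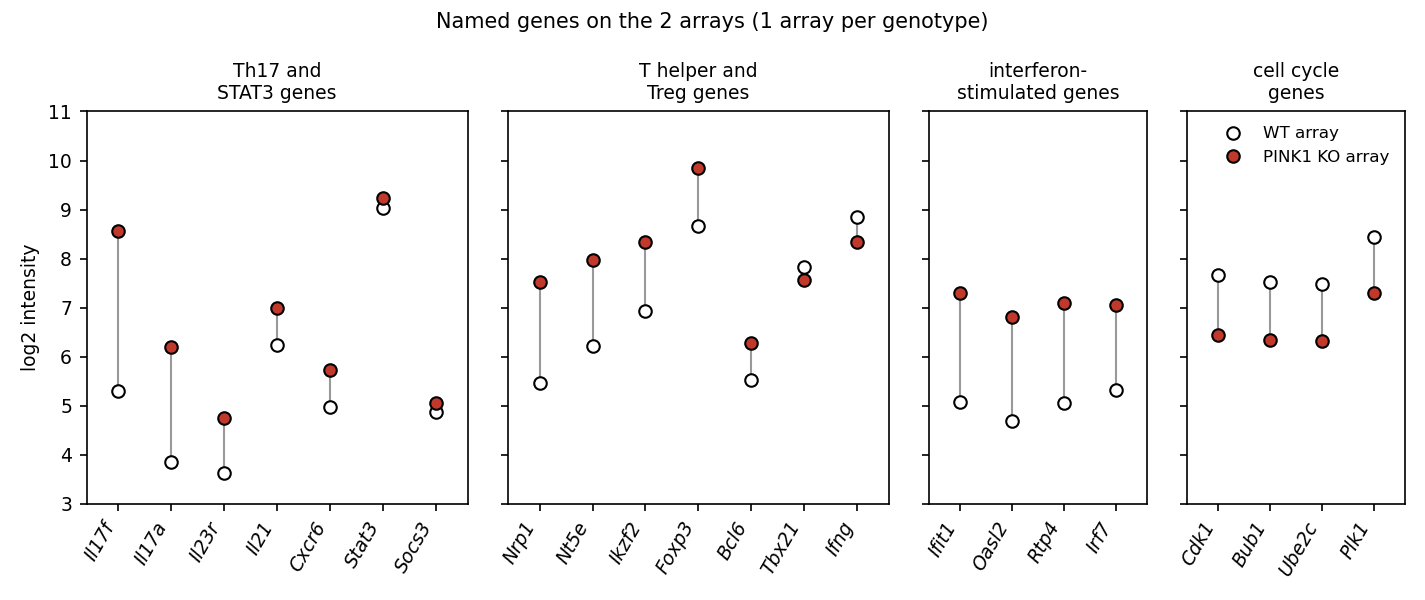
Log2 intensity (y axis) of named genes on the WT array (open circles) and the PINK1 KO array (red circles), with 1 array per genotype and grey lines joining the pair. Among the genes drawn here, Il17f shows the widest gap (5.30 and 8.56), Stat3 a small gap (9.04 and 9.24), and the 4 cell cycle genes lie lower on the PINK1 KO array.

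Regulatory T cell genes were higher as a group. Foxp3, the lineage factor of these cells, was 8.67 on the WT array and 9.85 on the PINK1 KO array, or 2.28-fold higher. Nrp1 was 4.17-fold higher, Nt5e, the ectoenzyme CD73, 3.39-fold higher, and Ikzf2, the transcription factor Helios, 2.65-fold higher. Of 19 members, 9 were 1.5-fold or more higher, 9 lay between and 1 was lower. The median of 0.51 was above all 10000 random lists. Il10, an anti-inflammatory cytokine gene on this list, differed by -0.06, and its sign turned to 0.06 under another scaling. Macrophage and neutrophil markers, with medians of 0.52 and 0.37, and B cell markers, with 0.31, were higher beside this list.

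Follicular helper genes were higher too. Bcl6, the lineage factor of follicular helper cells, and Il21 were both 0.76 higher, the follicle-homing receptor gene Cxcr5 was 0.82 higher and Cd40lg, which gives help to B cells, 0.69 higher. Of 13 members, 7 were 1.5-fold or more higher and 6 lay between, and the median of 0.59 was above all 10000 random lists. Markers of B cells, the partners of follicular helper cells, had a median of 0.31 and MHC class II genes of 0.30 on the same arrays, beside the macrophage median of 0.52 and the neutrophil median of 0.37.

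The Th1 and Th2 lists moved less. Tbx21, the lineage factor of Th1 cells, differed by -0.28 and its target cytokine gene Ifng by -0.51, while the chemokine receptor gene Cxcr3 was 0.94 higher, Il18r1 0.83 higher and Il12rb2 differed by -0.72. Among 14 Th1 members, 2 were 1.5-fold or more higher, 11 lay between and 1 was lower. The Th1 median of -0.17 lay at percentile 15.8 of random lists, and without Cxcr3 it was -0.27 at percentile 2.4. Other settings made it smaller. It was -0.05 with the trend on level removed (percentile 27.1) and -0.07 for members above the filter (percentile 62.2). The mean of the list was -0.02 (percentile 72.4). Gata3, the lineage factor of Th2 cells, was 0.29 higher and Il4 0.25 higher, both within 1.5-fold, while Il9 (0.98) and Il3 (0.92) were the highest of the Th2 list. Among 12 Th2 members, 2 were 1.5-fold or more higher and 10 lay between, with a median of 0.22 at percentile 99.9, below the medians of the macrophage (0.52), neutrophil (0.37) and B cell (0.31) lists.

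Effector and memory genes were higher as a group. The granzyme gene Gzmk was 2.51-fold higher, the calcium-binding protein gene S100a6 1.99-fold higher and Prdm1, the transcription factor Blimp-1, 1.98-fold higher, while Gzmb, the granzyme of activated cytotoxic cells, was 2.13-fold lower. Of 19 members, 8 were 1.5-fold or more higher, 10 lay between and 1 was lower, and the median of 0.42 was above all 10000 random lists. The macrophage and neutrophil lists, with medians of 0.52 and 0.37, and the B cell list, with 0.31, were higher too. Among naive T cell genes, S1pr1, the receptor for exit from lymphoid organs, was 2.76-fold higher and the interleukin 7 receptor gene Il7r 2.16-fold higher, while the other 10 of 12 members lay within 1.5-fold. The naive list had a median of -0.12 at percentile 52.2.

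T cell receptor and co-stimulation genes stayed within 1.5-fold in all 17 members, with Thy1 (0.38), Cd2 (0.30), Prkcq (0.26) and Cd28 (0.24) the farthest from 0. Their median was 0.05, at percentile 99.4 of lists matched on level and at percentile 73.4 of lists not matched on level, and it was 0.20 with the trend on level removed. Early activation genes had a median of -0.02 at percentile 97.4, and the median turned positive, up to 0.12, under some other scalings. In that list the chemokine gene Xcl1 was 2.73-fold higher, Tnfaip3, an inhibitor of NF-kappa B, was 0.71 higher, and the activation-induced factors Nr4a2 and Egr1 differed by -0.65 and -0.56. Il2, the growth factor gene of activated T cells, differed by -0.47. Immediate early and heat shock genes, which respond to handling of cells, all lay within 1.5-fold, with a median of 0.04 at percentile 96.8.

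Interferon-stimulated genes were higher as a group. Ifit1, Oasl2 and Rtp4, which respond to type I interferon, were 4.69-fold, 4.35-fold and 4.08-fold higher, and Irf7, a transcription factor of the interferon response, was 3.33-fold higher. Of 25 measured members, 12 were 1.5-fold or more higher, 9 of them 2-fold or more, 13 lay between and 0 were lower. The median of 0.58 was above all 10000 random lists, whose middle 95% ran from -0.20 to 0.06. The members differed in size, and the interferon-induced genes Rsad2 and Ifit3 were both only 0.12 higher. The macrophage, neutrophil and B cell lists, with medians of 0.52, 0.37 and 0.31, were higher on the same array.

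Cell cycle genes were lower as a group. The mitotic kinase genes Cdk1, Bub1 and Plk1 were 2.33-fold, 2.25-fold and 2.19-fold lower, and Ube2c, which acts in the exit from mitosis, was 2.22-fold lower. The proliferation marker Mki67 differed by -0.89 and the replication factor gene Pcna by -0.36. Of 29 members, 22 were 1.5-fold or more lower, 7 lay between and 0 were higher, and all 29 were below their WT level under each scaling tried. The median of -0.90 was below all 10000 random lists, whose middle 95% ran from -0.27 to -0.03. With the trend on level removed the median was -0.74.

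Genes of energy metabolism were lower by smaller amounts. Among 51 oxidative phosphorylation genes, 49 were below their WT level, 46 after quantile normalization and 43 with the trend on level removed. The subunit genes Ndufb5 (-0.66), Ndufa10 (-0.58) and Ndufs8 (-0.56) of respiratory complex I and Sdhb (-0.58) of complex II were the lowest, and 50 of the 51 lay within 1.5-fold. The list's median was -0.31, below 9999 of 10000 random lists, and it was -0.19 with the trend removed. The 10 mitochondrially encoded transcripts differed by 0.00 to 0.19, with ND4L (0.19), COX3 (0.18) and ND6 (0.17) the highest. Their median of 0.08 lay at percentile 99.0, and it was 0.01 at percentile 86.9 after quantile normalization. Glycolysis genes had a median of -0.30 at percentile 0.3, or -0.17 with the trend removed, with 2 of 18 members 1.5-fold or more lower, Eno3 (-0.80) and Tpi1 (-0.63), and 16 between. Housekeeping genes had a median of -0.27, or -0.12 with the trend removed. Of their 11 measured members 4 are on other fixed lists, among them Sdha (oxidative phosphorylation) and Gapdh and Pgk1 (glycolysis). The comparison with them is therefore not independent.

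Genes of mitophagy, the pathway that PINK1 starts, lay near the middle of random lists as a group. The mitophagy receptor gene Bcl2l13 differed by -0.64, and the other 32 of 33 measured members lay within 1.5-fold, among them Atg12 (-0.46), Phb2 (-0.37) and Tomm20 (-0.36). The median of -0.11 lay at percentile 46.4. Prkn, the ubiquitin ligase that PINK1 activates, was not analysed here. In the list of the mitochondrial and integrated stress response, Asns, an amino acid synthesis gene that ATF4 induces, differed by -0.83 and the serine pathway genes Shmt2 and Psat1 by -0.60 and -0.50. That list had 2 of 20 members 1.5-fold or more lower and 18 between, with a median of -0.23 at percentile 1.6, or -0.13 at percentile 2.9 with the trend on level removed. Antioxidant genes had a median of -0.23 at percentile 7.2, although Hmox1, the heme oxygenase induced by oxidative stress, was 2.72-fold higher and the other 18 members lay within 1.5-fold. The antioxidant median was -0.07 with the trend on level removed (percentile 17.0) and -0.14 after quantile normalization (percentile 19.4). The mean was -0.09 (percentile 54.9).

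**Figure D3:**
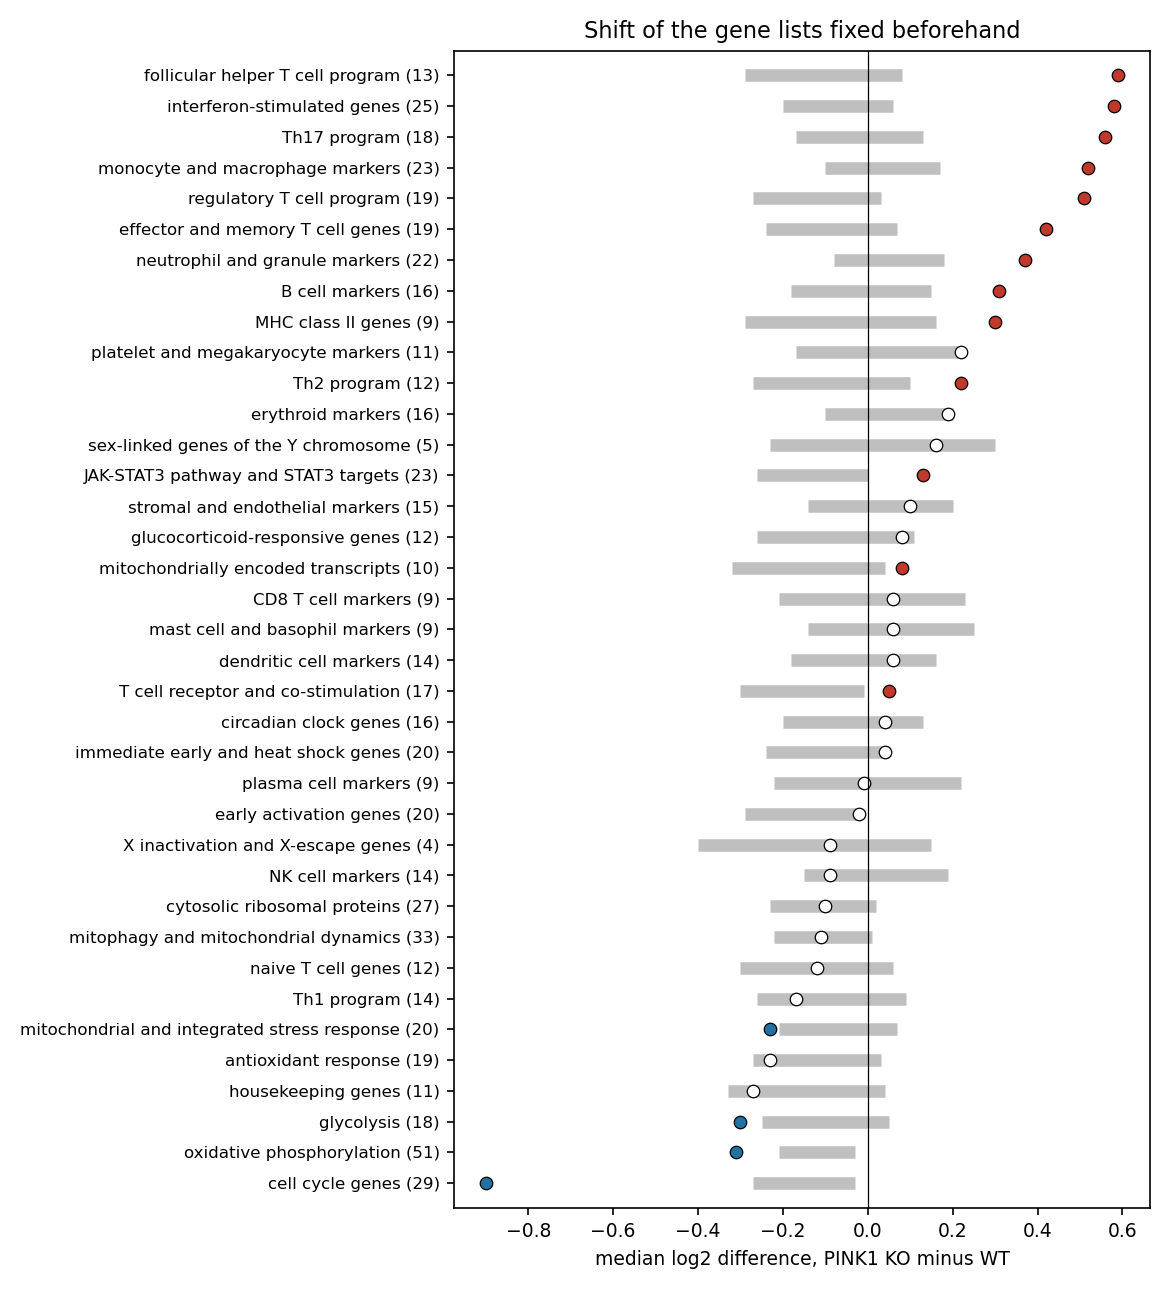
Median log2 difference, PINK1 KO minus WT (x axis), of each of the 37 gene lists fixed beforehand, with the number of measured members in brackets and grey bars for the middle 95% of 10000 random lists matched on level. Filled circles mark the 17 lists outside that range (red 13 above, blue 4 below), from 0.59 for follicular helper genes to -0.90 for cell cycle genes.

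Markers of other cell types were measured in the same RNA. Among 23 monocyte and macrophage markers, 11 were 1.5-fold or more higher and 12 lay between, with a median of 0.52 above all 10000 random lists. Cybb, a subunit of the phagocyte oxidase, was 3.65-fold higher, the adhesion molecule gene Vcam1 2.01-fold, the lysosomal protease gene Ctss 1.93-fold and the lysosomal protein gene Cd68 1.83-fold. Of 22 neutrophil and granule markers, 8 were 1.5-fold or more higher and 14 lay between, with a median of 0.37 above all 10000 random lists. S100a8 was 3.82-fold higher, Ngp 3.58-fold, Chil3 2.65-fold and Lcn2 2.46-fold, and all of these but Lcn2 lay below the level filter on the WT array. Only 9 of the macrophage markers, with a median of 0.81, and 9 of the neutrophil markers lay above the level filter. That filter uses the mean of both arrays, so high PINK1 KO values help members to pass and raise such a median. On the WT array 7 macrophage and 5 neutrophil markers reached it. The mean of the neutrophil list was 0.61. Without the genes of the lists of other cell types, a setting chosen after seeing the data, 105 genes were 2-fold or more higher and 44 lower. This setting took out only the listed genes, leaving 11007 of 11090, and kept Ptgs2, Nos2 and Il1a. It cannot show how many of the differences come from other cell types.

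B cell markers had 2 of 16 members 1.5-fold or more higher, the receptor gene Cd22 (0.78) and the B lineage factor Pax5 (0.73), and 14 between, with a median of 0.31 above 9995 of 10000 random lists. MHC class II genes had a median of 0.30 at percentile 99.8, and H2-Ob (0.98) and H2-Aa (0.65) were the 2 of 9 members that were 1.5-fold or more higher. Dendritic cell markers had a median of 0.06 at percentile 80.3, with Itgax, the integrin CD11c, 2.13-fold higher from a WT intensity of 4.23 below the level filter, and the transcription factor gene Irf8 at -0.51, or -0.20 by its probe set with the highest mean. The plasma cell (-0.01, percentile 48.1), CD8 T cell (0.06, percentile 67.7), NK cell (-0.09, percentile 10.2), stromal and endothelial (0.10, percentile 77.4) and mast cell and basophil (0.06, percentile 51.7) lists lay within the middle 95% of random lists. The plasma cell median does not settle that list, since 4 members were higher and 5 lower, and Ighg1 and Igha were not measured. Jchain was more than 2-fold higher at a level below the filter, and Derl3 differed by -0.57. The mean was 0.17, and plasma cell members above the filter had a median of -0.32 at percentile 4.5. A probe set shared by immunoglobulin kappa segments was 1.71 higher. Erythroid markers had a median of 0.19 at percentile 97.1, with Car2 2.63-fold higher from a WT intensity of 4.15 below the level filter, and platelet markers a median of 0.22 at percentile 97.4.

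Control lists stayed within the middle 95% of random lists. Cytosolic ribosomal protein genes had a median of -0.10 at percentile 51.3 and housekeeping genes lay at percentile 12.5. Circadian clock genes, which follow the hour of sampling, had a median of 0.04 at percentile 81.5, with Npas2 at -0.80 and Nr1d1 at 0.74. Glucocorticoid-responsive genes, which follow stress of the animal, had a median of 0.08 at percentile 95. In that list Il7r was 2.16-fold higher, Txnip was 0.71 higher and Errfi1 differed by -0.61. Without Il7r, the member with the largest difference, the median was 0.03 at percentile 84.1. Genes of the Y chromosome (median 0.16, percentile 85.4) were below the level filter on average over both arrays, and Xist was 10.08 on the WT and 10.39 on the PINK1 KO array. The list of X inactivation and X-escape genes had a median of -0.09 at percentile 68.2, which turned to 0.07 under another scaling. Of the 37 lists, 17 lay outside the middle 95% of random lists, 13 above and 4 below. If members were as independent as randomly drawn genes, 1.9 of 37 would. Genes of a list can move together and lists share genes, so 17 cannot be judged against 1.9.

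Genes near Pink1 were examined because a knockout line can carry flanking sequence of another strain. Within 10 Mb of Pink1, 0 of 189 genes differed by 2-fold or more, against 158 of 10884 elsewhere (1.45%), which would give 2.7 genes in a window of that size. Within 5 Mb there were 0 of 94 and within 20 Mb 0 of 349.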

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

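The tests of myeloid transcripts, of scatter among dim probe sets and of the share of T cells were chosen after the results they bear on were seen. Those of gamma delta T cell markers and of the trend with level are recorded as written before. The scatter test replaced an earlier count, in which 1 of 2218 genes of similar mean level, the gene itself, differed by as much as Il17f or as Il17a. The myeloid and gamma delta marker lists were written after the fixed lists had been looked at. Il17a and Il17f are on a fixed list, so the gamma delta test was not blind to the pattern it bears on.

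Differences also appeared in probe sets that entered no gene value. Of 6933 probe sets with no gene listed above the level filter, 141 were 2-fold or more higher on the PINK1 KO array and 78 were lower. Together this is a larger share than the 1.42% among genes, and whether such probe sets are noisier could not be judged. The largest difference was 3.70, from a log2 intensity of 4.35 to 8.05, which is above the 3.26 of Il17f. It comes from 1 probe set whose target is unknown. Of 1170 probe sets that list several genes, 21 were 2-fold or more higher and 5 were lower. The higher ones included probe sets shared by the interferon-induced genes Ifi211 and Ifi204 (1.98), by Ifi27l2a and Ifi27l2b (1.78) and by the MHC class I genes H2-Q6 and H2-Q8 (1.68). They also included probe sets shared by immunoglobulin kappa chain segments (1.71 and 1.36), by immunoglobulin heavy chain genes (1.01), and by the alpha globin genes Hba-a2 and Hba-a1 (1.01). The lower ones included probe sets shared by replication-dependent histone genes of the H2A (-1.45) and H3 (-1.42) families.

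Il17a and Il17f were higher on the PINK1 KO array, while most genes of the STAT3 pathway differed little. For Il17f, the test spoke against scatter of dim probe sets, since its lower intensity of 5.30 was above the level filter of 4.61. Both values were known when that test was written. The filter is the median level of genes and no detection limit, so the test does not decide the question. Scatter also stays open for Il17a, at 3.85 on the WT array, and an error of a single probe set has no replicate to check it. More gamma delta T cells, another source of interleukin 17, stay open, since their 6 measured markers had a median difference of 0.35 at percentile 99.1 of matched random lists, between the values that would have spoken for and against them. Trgv6 (0.67), 5830411N06Rik (0.47) and Sox13 (0.40) were the highest of these, 3 of the 6 reached the level filter on the WT array, Blk and Zbtb16 are on other lists, and a sort for CD4 would remove most such cells. An effect of PINK1 loss on Th17 cells is the explanation the design names, and it stays open and untested, as does a difference between animals.

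Inflammatory myeloid genes were higher on the PINK1 KO array, such as Ptgs2 (2.65), Nos2 (2.34), Il1a (2.09) and Cybb (1.87). More myeloid cells in the PINK1 KO sample may account for this, and a set of 12 abundant myeloid transcripts, 10 of which are on other lists, had a median difference of 0.20 at percentile 96.2, which does not decide it. Ms4a6c (1.05), C1qb (0.81) and Lyz2 (0.60) were higher while C1qa (-0.30), Tyrobp (-0.21) and Cst3 (-0.05) were not, and only 5 of the 12 reached the level filter on the WT array. A sort for CD4 would remove most myeloid cells, but how the cells were purified is not given in the sources used here. A change of gene activity in the T cells stays open as well and was not tested.

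Cell cycle genes were lower on the PINK1 KO array. A lower share of T cells is argued against as the whole cause. The median of the T cell receptor and co-stimulation list lay 0.95 above that of the cell cycle list, with a robust SD of 0.16 among the T cell receptor genes. Both medians were known when that test was written, and a part played by a smaller loss of T cells was not tested. A trend with the mean level is also argued against as the whole cause, since the median was -0.74 with that trend removed. Fewer dividing T cells at the time of harvest, through the genotype or through the culture, activation state or animal, is a candidate explanation that the design cannot resolve.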

How the results depend on the processing

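Leaving out replicates was not possible with 1 array per genotype. No paired analysis was possible because no result comes from a test and each genotype has 1 array. The pseudocount alternative was not run because the values are on a log scale. Among named genes, 667 of 668 values under other settings moved by less than the spread of genes of similar level. The exception was Irf8. Many of these values could hardly move by construction. Centring shifted every gene by the same small amount, the median difference over all genes of -0.005. Only Socs3, Gata3, Edem1, Irf8 and Cd209a of these genes had more than 1 probe set, so the choice of probe set could change no other. The signs of Il10, Edem1 and Cd8a turned under some scalings. Of 297 list values under other settings, 279 kept their side of the percentile limits, and 14 of the 17 lists that lay apart did so under every planned setting. The 37 values under centring could not change side, since a list and its random lists shift alike. Lists wholly above the filter could not change when only members above it were used. The 297 also include settings chosen after seeing the data. The 114 higher and 44 lower genes became 132 and 28 with the trend on level removed, 47 and 25 with a filter at the 75th percentile, 400 and 453 at 1.5-fold, and 35 and 4 at 3-fold (by construction, except for the trend, where the cause was not tested). With each of 19896 probe sets counted on its own, 284 were higher and 132 lower. That count took in probe sets with no gene listed (141 higher and 78 lower) and with several genes (21 and 5). It is therefore no check of the averaging per gene. Mitochondrially encoded transcripts no longer lay apart after quantile normalization (0.01), with the trend removed (0.14) or against lists not matched on level (0.08). The same held for the T cell receptor list against lists not matched on level (0.05), and for the stress response list with the trend removed (-0.13) or with its members above the filter (-0.23). Lists that lay apart only under an alternative were Th1 (-0.27), immediate early (0.07) without their largest member, immediate early (0.09) and platelet (0.35) with members above the filter, early activation (0.03), erythroid (0.20) and platelet (0.25) as means, early activation with the probe set of highest mean (0.02), and antioxidant (-0.23), housekeeping (-0.27), erythroid (0.19) and platelet (0.22) lists against lists not matched on level. The cause was not tested for these lists. The mean had the opposite sign to the median in the naive (0.04), plasma cell (0.17), NK cell (0.11) and early activation lists. Signal over background could not be judged, so values of dim genes such as Il17a on the WT array (3.85) are the least certain.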

Other observations

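The gene groups in this part were chosen after some or all of their values were seen, except the TGF-beta and the ribosome biogenesis groups. Some further interferon-induced families were examined. The HIN-200 genes, which include sensors of cytosolic DNA, had a median difference of 1.05 over 10 measured members, with Ifi209 at 1.92, Ifi213 at 1.38 and Ifi202b at -0.66, and 5 of the 10 lay below the level filter. The Schlafen genes, a family with members that keep T cells quiescent, had a median of 0.43 over 8 members, with Slfn5 at 2.12 and Slfn1 at 1.32 but Slfn3 at -0.50. Interferon-induced GTPases, 3 of which are on the fixed interferon list, had a median of 0.18, and 11 of 14 lay within 1.5-fold. MHC class I genes had a median of 0.13, and 12 of 15 lay within 1.5-fold, while Nlrc5, the activator of MHC class I transcription, was at 0.91. Inflammasome and interleukin 1 genes had a median of 0.27, and 11 of 18 lay within 1.5-fold. Casp1 (2.05), Il1r2 (1.79), Casp4 (1.77) and Il1b (1.67) were high among them, while Myd88 (-0.30), Nlrp3 (-0.17) and Il18 (-0.11) lay below their WT level. Macrophage markers, with a median of 0.52, were higher on the same array, and a group of 12 myeloid inflammatory genes picked for its high values had a median of 1.81.

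Among genes lower on the PINK1 KO array, mitosis and DNA replication differed in size. All 27 measured mitotic genes were 1.5-fold or more lower, with a median 1.99-fold lower, but 16 of them are also on the fixed cell cycle list. Kif23 (-1.30), Kif14 (-1.17) and Hmmr (-1.13) were among the lowest. The 28 DNA replication genes, 6 of them on that list too, had a median of -0.46, with Rfc2 at -0.80 and Prim2 at -0.71, and all 28 were below their WT level. Among 19 cholesterol and fatty acid synthesis genes, 4 were 1.5-fold or more lower, Elovl6 (-0.88), Lss (-0.71) and Hmgcs1 (-0.70) among them, and 15 lay between, with a median of -0.35 beside -0.27 for housekeeping genes. Ribosome biogenesis and MYC-responsive genes had a median of -0.27 at percentile 5.7 of random lists, and TGF-beta pathway genes a median of 0.12 at percentile 98.7, with Tgfbr2 at 0.73. The medians of these gene groups kept their sign under each scaling tried, but removing the trend on level moved several. They became -0.11 for ribosome biogenesis, -0.22 for cholesterol and fatty acid synthesis, 0.33 for interferon-induced GTPases, 0.27 for MHC class I and 0.26 for TGF-beta pathway genes, and after quantile normalization the medians of MHC class I and TGF-beta pathway genes were 0.20 and 0.19.

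Among classes of genes that were left out of the named genes, 10 of 714 predicted genes or clones were 2-fold or more higher and 1 was lower, 4 of 208 small RNA genes were higher, and 2 of 19 antigen receptor segments were higher. Jchain, a plasma cell gene, was 2.39 higher at a level below the filter. Of the 118 olfactory, vomeronasal and taste receptor genes above the filter, 0 differed by 2-fold.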
